A study of Bos taurus with 9 samples.

How the data were processed

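Gene expression was measured in 9 samples of co-cultured bovine endometrial stromal and epithelial cells, hybridised to an Affymetrix bovine expression array with 1 array per sample. Per the labels' protocols, endometrium came from 9 cows on days 2 to 5 of the oestrous cycle, stromal and epithelial cells were seeded together at a ratio of 3 to 1, and cells were exposed for 6 h before RNA was extracted. Each sample was a pool of RNA from 3 cows, and 100 ng of RNA per sample was amplified and labelled with biotin. The samples were grouped by the labels into a control group given phosphate-buffered saline (PBS), a group given lysophosphatidic acid (LPA, 1e-06 M) and a group given LPA together with interferon tau (IFNt, 1000 antiviral units, with no volume stated), with 3 samples in each group. A group given interferon tau alone was not analysed here, so the effect of interferon tau without LPA and an interaction of both agents could not be estimated.

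The values used were the deposited log2 expression values of each probe set on each array, made with RMA in Partek per the submitters' processing notes. RMA corrects the background, makes the distributions of the arrays alike by quantile normalization and summarises the probes of a probe set. The software versions are not given in the sources used here, and base 2 was taken from the usual output of RMA and from the range of the values. Array medians lay between 4.30 and 4.38, so a change that moves most transcripts in one direction would be hidden by the normalization. No detection call was used, and no genome coordinates are given because the sources used here name no build. The number of arrays limits the precision of every comparison.

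Of 24128 probe sets, 112 Affymetrix control probe sets were left out of the comparisons and 24016 were tested. Gene names came from the array's annotation, brought up to date through gene identifiers in the RefSeq table of the ARS-UCD2.0 assembly, which held 13283 of the 13318 entries with 1 symbol and changed 0 symbols. Among the tested probe sets 13292 had 1 gene symbol, 86 had several and 10638 were unnamed, and no gene was named from a probe set with several symbols. The named probe sets covered 9155 genes.

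Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the log2 values of all 9 arrays, which share 1 estimate of the spread per probe set, with no covariate and no filter on dim probe sets. The comparisons were LPA against control, LPA+IFNt against control and LPA+IFNt against LPA, with a moderated F test for any difference among the 3 groups. P-values were adjusted by the Benjamini-Hochberg method over the 24016 probe sets within each comparison, and the threshold was 0.05. Fold changes are differences of group means on the log2 scale, with the standard error (SE) from the model. The labels give 9 cows for 9 pools of 3 cows each, so the pools must share cows and are not all independent. P-values of the fit without a block measure the spread between these pools and take no account of that sharing.

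Lists of genes were fixed before the data were examined: interferon-stimulated antiviral genes, interferon receptor, JAK-STAT and IRF genes, MHC class I antigen presentation, chemokines and cytokines, NF-kappaB targets, LPA receptors, synthesis and breakdown, prostaglandin synthesis, transport and receptors, immediate early genes, SRF and YAP targets, proteases, inhibitors and matrix, growth factors and implantation-related genes, steroid and oxytocin receptors, sterol synthesis genes, ER stress and amino acid response, apoptosis genes and cell cycle genes. Marker lists of endometrial epithelial, endometrial stromal, leukocyte, endothelial, red blood cell, and smooth muscle and pericyte cells were fixed with them. Each list was tested with camera in limma with a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, with the brightest probe set standing for a gene. An estimated correlation and limma's fry were run beside it. The lists hold members that the array did not name, so the number measured is given with each list.

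Named genes were also chosen by a rule fixed before the data were examined. In each comparison the text takes the 12 higher and the 12 lower named genes with the largest change among those past the threshold whose 3 arrays of one group all lay above the 3 of the other, a gene counting once by its most changed probe set. From each list it takes up to 4 members with the largest change past the threshold, or the 2 members with the smallest p where none passed. LPAR1, LPAR2, LPAR4, LPAR5, LPAR6, ENPP2, PTGS2, IFNAR1, IFNAR2, ISG15, MX1 and MX2 are always given, as values. LPAR3 was in the rule too, but no probe set carried its name alone, so it was not measured here.

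Replicate numbers in the labels were checked for pairing before the fits with and without them were compared. All 9 pairs of arrays from different groups with the same number had positively correlated deviations from their group means (r across probe sets 0.19 to 0.49, median 0.39), whereas the 18 pairs with different numbers had r from -0.47 to 0.14. The numbers were therefore taken to pair the samples. The counts of cows mean that samples shared cows, but the labels do not say which, so pairing by number is an inference from the data. The main fit, fixed before the data were examined, has no block, and the fit with the replicate block is given beside a result where it changes the call.

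The model was checked on simulated data with the real means and spreads. Of 50 probe sets changed by 0.5 on the log2 scale it recovered 70% for LPA against control, 64% for LPA+IFNt against control and 64% for LPA+IFNt against LPA, and of those changed by 1 it recovered 96%, 94% and 96%. False calls made up 4.2%, 4.8% and 7.3% of the calls. A list shifted by 0.5 was found and 0 of the 21 other lists were called. The simulation drew genes and arrays independently, without pairing by replicate number. It therefore does not measure false calls that correlated genes or paired samples would give.

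Alternatives fixed before the data were examined were quantile normalization again, centring on array medians, 2 filters on dim probe sets, an intensity trend with robust variances, no variance moderation, array weights, only the 6 arrays compared, the replicate number as a block, averaging the probe sets of a gene, stricter thresholds, fry, an estimated inter-gene correlation and leaving out each array in turn. Centring on 12 poly-A spike-in probe sets, alone or with the replicate block, and the replicate block together with an estimated correlation, were added after the data were seen. Spike-in centring adds 1 shift to all probe sets of an array, so limma gave all of them the same standard error, and calls lost with it do not measure the shift alone.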

Results

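The data set consisted of 9 arrays of endometrial cells from cows, with 3 pooled samples each for control, LPA and LPA+IFNt. LPA is a signalling lipid that acts through a family of G protein-coupled receptors, and interferon tau is the type I interferon with which the ruminant embryo signals pregnancy to the uterus. Over the 24016 probe sets the arrays correlated with r of 0.9983 to 0.999 within control, 0.9965 to 0.9979 within LPA and 0.998 to 0.9988 within LPA+IFNt. Between groups, r was 0.9954 to 0.9989 for control and LPA, 0.992 to 0.9937 for control and LPA+IFNt, and 0.9909 to 0.9939 for LPA and LPA+IFNt. No 2 arrays held the same values. The moderated F test called a difference among the 3 groups for 1439 probe sets, or 2276 with the replicate number as a block, and 911 or 933 without LPA+IFNt replicate 1 or replicate 3.

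The first comparison asked how the cells responded to 6 h of LPA. IER2, an immediate early gene, rose by 1.05 on the log2 scale, from 8.87 ± 0.07 in control to 9.93 ± 0.03 with LPA (SD, n = 3, adjusted p = 0.0106). UTP6, which takes part in processing of ribosomal RNA, was higher by 2.17 (SE 0.20, adjusted p = 0.0171), and ANKH, a membrane protein of pyrophosphate export, by 1.46 (SE 0.12, adjusted p = 0.0121). The other named genes that rose were SH3GLB1 (0.96), the HSP90 co-chaperone gene AHSA1 (0.71), GTPBP4 (0.70), ARPC1A (0.49), which encodes a subunit of the actin-nucleating Arp2/3 complex, UFC1 (0.46) and PPM1B (0.39). Named genes that fell were the nucleoporin gene NUP214 (-1.81, SE 0.15, adjusted p = 0.0117), SETD5 (-1.01), the amyloid precursor gene APP (-0.86) and SLC25A5 (-0.83), the gene of a mitochondrial ADP/ATP carrier. Brighter probe sets of ANKH (mean level 8.95) and SLC25A5 (13.47) had log2 fold changes near 0 (-0.004 and -0.04), and with the probe sets of each gene averaged ANKH stood at 0.73 (adjusted p = 0.144).

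In all, 17 probe sets passed the threshold with limma in LPA against control, 12 higher and 5 lower, and 4 of them were unnamed. Of the 24016 probe sets, 1993 probe sets had an unadjusted p under 0.05, where 1201 would be expected by chance. The 3 LPA arrays lay apart from the 3 control arrays for 10% of probe sets. Chance gives 10% for exchangeable arrays, and the 3 other splits that keep the replicate numbers apart gave 1.9% to 5.8%. The remaining splits, which part only 1 pair of equal number, gave 3.4% to 35.8%, so the highest lay above the real grouping. The count depended on single arrays: it was 0 without control replicate 2 (1520 at an unadjusted p under 0.05) and 0 without LPA replicate 1 (1739), 8 without control replicate 1, 11 without LPA+IFNt replicate 1 or 3, 28 without control replicate 3 and 169 without LPA replicate 2. It was 11 with the replicate number as a block, where UTP6 (adjusted p = 0.0675), ANKH (0.0626), SH3GLB1 (0.0675), GTPBP4 (0.0626), UFC1 (0.0626), PPM1B (0.0725), NUP214 (0.0626), SETD5 (0.0675) and SLC25A5 (0.0675) missed the threshold, and 0 with no variance moderation (1476 at an unadjusted p under 0.05). None of the 13 named genes kept its call with each array left out: all 13 lost it without control replicate 2 and without LPA replicate 1, with highest adjusted p of 0.0698 to 0.15. Fewer lost it without control replicate 1 (9), control replicate 3 (3), LPA replicate 3 (1) or any 1 of the LPA+IFNt arrays (5 each). With spike-in centring 6 of the 13 were lost: SH3GLB1 (0.87), AHSA1 (0.62), GTPBP4 (0.62), ARPC1A (0.40), UFC1 (0.37) and PPM1B (0.30). Their changes were only slightly smaller, and all probe sets had the same standard error in that fit.

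The measured genes of LPA receptors, which did not include LPAR3, and of LPA metabolism were not called after LPA. LPAR6 stood at 7.31 in control and 6.59 with LPA (log2 fold change -0.72, SE 0.11, adjusted p = 0.0819). LPAR1 (0.08), LPAR2 (-0.11), LPAR4 (0.03), LPAR5 (0.07) and ENPP2 (-0.04), the gene of the LPA-producing enzyme autotaxin, all had adjusted p of at least 0.765. LPAR4 and LPAR5 had control levels of 2.37 and 2.19, below the highest value of the 3 probe sets for a bacterial trp transcript (2.80). PTGS2, which encodes the inducible cyclooxygenase of prostaglandin synthesis, was at 12.98 in control and 13.21 with LPA (adjusted p = 0.696), and AKR1C4 had a log2 fold change of -0.42 (adjusted p = 0.614). The list of LPA receptors, synthesis and breakdown (12 genes measured, median -0.02) and that of prostaglandin synthesis, transport and receptors (17 genes, median -0.01) did not pass camera (adjusted p = 0.662 and 0.987).

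Several lists moved slightly in LPA against control, by camera with the preset correlation. Higher were proteases, inhibitors and matrix (26 genes, median 0.12, adjusted p = 7.49e-05), endometrial stromal markers (15 genes, median 0.08, adjusted p = 0.00259), SRF and YAP targets (19 genes, median 0.05, adjusted p = 0.00331), NF-kappaB targets (15 genes, median 0.15, adjusted p = 0.00382), chemokines and cytokines (25 genes, median 0.13, adjusted p = 0.00542), growth factors and implantation-related genes (34 genes, median 0.02, adjusted p = 0.0226) and interferon-stimulated antiviral genes (41 genes, median 0.04, adjusted p = 0.0245). Cell cycle genes were lower (28 genes, median -0.22, adjusted p = 2.79e-05). None of these 8 calls held with an estimated correlation, where adjusted p lay between 0.441 and 0.465. With spike-in centring, which moved the median of all probe sets to -0.08, the medians of the SRF and YAP targets (-0.04), the stromal markers (-0.01), the growth factors (-0.06) and the interferon-stimulated genes (-0.04) changed sign. Calls were lost without LPA replicate 3 for chemokines and cytokines (adjusted p = 0.197), NF-kappaB targets (0.317), stromal markers (0.112) and interferon-stimulated genes (0.197), the last also without control replicate 3 (0.19) or LPA replicate 1 (0.0687). Growth factors lost theirs without control replicate 1 (0.161) or LPA replicate 2 (0.089). None of the members of these 8 lists passed over all genes. Adjusted over the list alone, 3 interferon-stimulated genes (RSAD2, ISG15 and SAMD9), 2 members of the protease list (PLAUR and SERPINE2), 1 NF-kappaB target (NFKBIE), 1 SRF and YAP target (TAGLN) and 1 stromal marker (THY1) passed. SAMD9 (0.39) was chosen after its values were seen.

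Members of those lists with the smallest p are given as values, none of them past the threshold. Log2 fold changes were 1.18 for RSAD2 (adjusted p = 0.0566), 0.71 for ISG15 (0.105), 0.27 for PLAUR (0.169), 0.22 for SERPINE2 (0.223), 0.52 for TAGLN (0.212), 0.55 for CALD1 (0.385), 0.30 for NFKBIE (0.216), 0.19 for CD40 (0.511), 0.24 for CSF2 (0.48) and -0.25 for IL18 (0.607). MX1 stood at 0.23 (0.649) and MX2 at 0.05 (1). The values were -0.24 for MSX1 (0.2), 0.61 for DKK1 (0.339), -0.38 for AURKB (0.307), -0.22 for MCM3 (0.362), 0.55 for the stromal marker THY1 (0.0713) and 0.55 for POSTN (0.432). RSAD2 passed (adjusted p = 0.0462) in the fit with probe sets averaged, but it has 1 probe set, so its own value was not averaged.

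The other lists did not pass in LPA against control. Immediate early genes stood at adjusted p = 0.0939 (18 genes, 1 higher, IER2, also adjusted over the list alone), or 0.0341 without LPA replicate 2. Steroid and oxytocin receptors had adjusted p of 0.103 (OXTR -0.41, NCOA1 -0.18), ER stress and amino acid response 0.103, or 0.0178 without LPA replicate 2 (ATF4 0.12, HSPA5 0.08), and interferon receptor, JAK-STAT and IRF genes 0.182 (IRF3 0.15, IFNAR1 0.34, IFNAR2 0.15). Apoptosis genes had 0.472 (BCL2 0.14, CFLAR 0.40), sterol synthesis genes 0.71 (DHCR7 -0.31, HMGCS1 -0.16) and MHC class I antigen presentation 0.826 (PDIA3 -0.24, TAP2 -0.21), none of these genes past the threshold over all genes. Adjusted over the list alone, DHCR7 and HMGCS1, PDIA3 and TAP2, and LPAR6 passed as lower. Among the marker lists that did not pass, adjusted p was 0.662 for endometrial epithelial (SPINT2 0.49, adjusted p = 0.0566, or 0.0452 with probe sets averaged, and CDH1 0.21, adjusted p = 0.0964), 0.113 for leukocyte (LCP1 0.60, PTPRC 0.75), 0.472 for smooth muscle and pericyte (DES 1.18, LMOD1 0.05), 0.574 for red blood cell (ALAS2 0.03, HBA 0.02) and 0.878 for endothelial markers (TEK 0.15, PECAM1 -0.05). In control 0 of 6 red blood cell, 0 of 11 endothelial and 6 of 19 leukocyte markers lay above the highest trp value (2.80), so the first 2 lists say nothing about those cells and the third rests on few genes. SPINT2 and CDH1 and LCP1 passed over their lists alone. SPINT2 has 1 probe set, so its own value was not averaged. The leukocyte list passed without control replicate 3 (0.0393) or LPA replicate 1 (0.0197). The prostaglandin list had a negative mean and median while its test pointed up, and the epithelial list a median of -0.03 with a mean of 0.01.

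**Figure D1:**
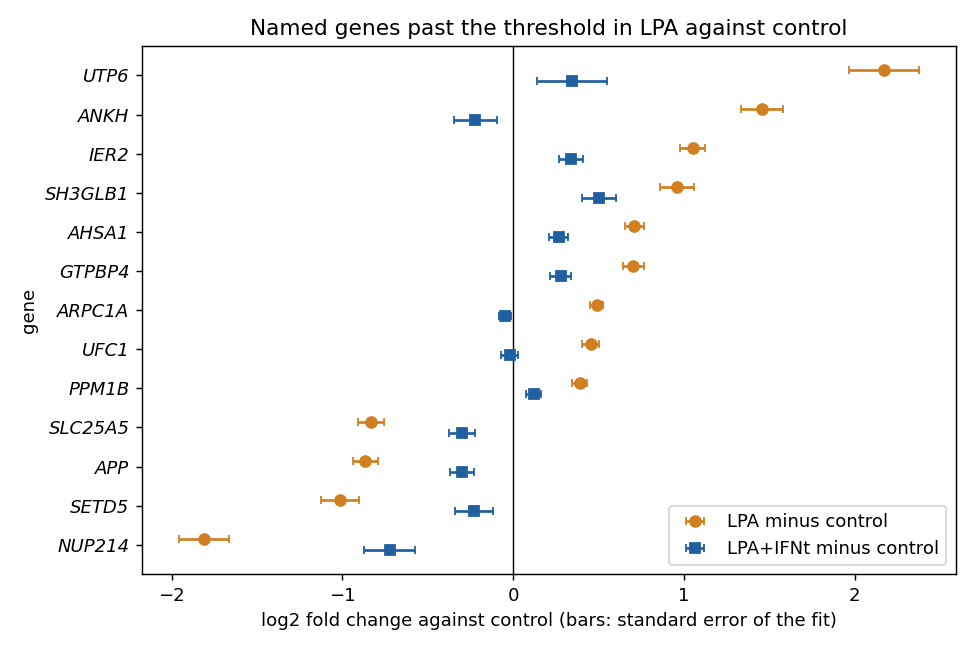
Log2 fold change against control (x axis) of the 13 named genes past the threshold in LPA against control (y axis), with circles for LPA, squares for LPA+IFNt and bars for the standard error of the model. UTP6 stands at 2.17 with LPA and 0.35 with LPA+IFNt, and ANKH at 1.46 and -0.22.

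The second comparison set LPA+IFNt against control, where genes of the antiviral interferon response rose by large factors in all 3 arrays. MX2, the gene of an antiviral GTPase, went from 2.12 in control to 9.71 (log2 fold change 7.59, SE 0.06, adjusted p = 3.96e-10), and the related MX1 from 7.47 ± 0.06 to 12.81 ± 0.23 (SD, n = 3). ISG15, a ubiquitin-like protein that is coupled to other proteins after interferon, rose from 7.93 ± 0.04 to 14.56 ± 0.12, which is 98.8-fold (adjusted p = 6.3e-08). PLAC8B (8.38), IFI44L (8.07), IFI44 (7.92), USP18 (7.80), whose protein removes ISG15 from its targets, RSAD2 (6.56), which encodes the antiviral enzyme viperin, IFI6 (6.42), LOC100298356 (6.38), IFI27 (5.96) and TNFSF13B (5.35), the gene of the B-cell survival factor BAFF, completed the 12 named genes with the largest rise. Control levels of CCL8 (2.20) and CD53 (2.75), named below, and of PLAC8B, IFI44L, IFI44, MX2 and LOC100298356 lay under the highest value of the trp probe sets (2.80), and counted from that value the rises were 2.54 for CCL8, 1.21 for CD53 and 7.51, 8.01, 7.40, 6.91 and 5.95 for the others.

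**Figure D2:**
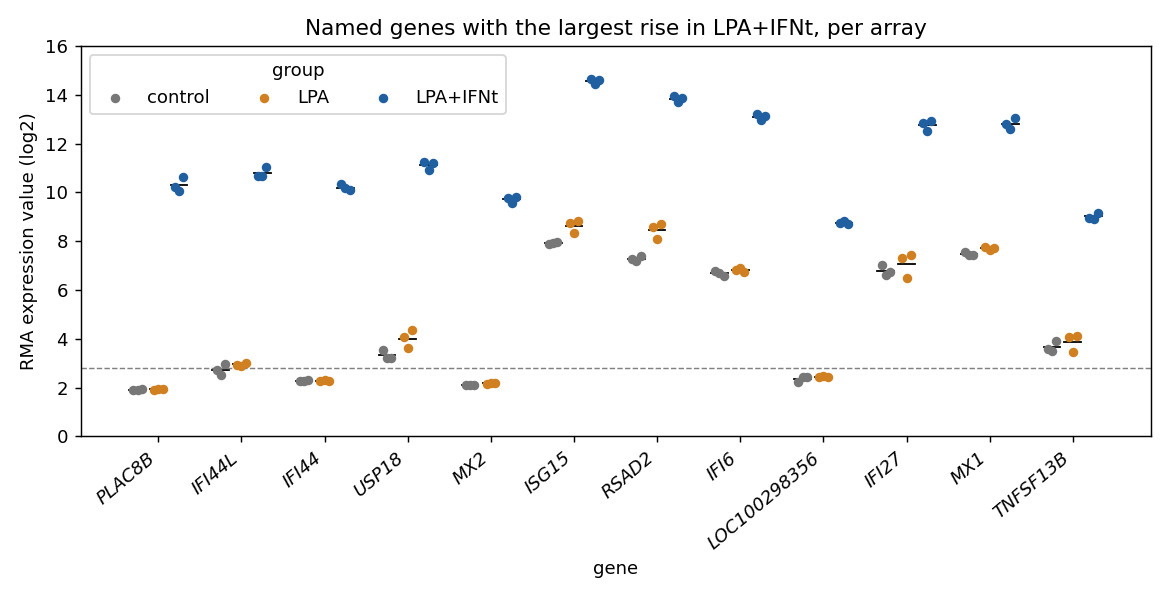
RMA values on a log2 scale (y axis) of the 12 named genes with the largest rise in LPA+IFNt against control (x axis), with 1 point per array, black bars for group means of 3 arrays and a dashed line at 2.80, the highest value of the trp control probe sets. ISG15 lies at 7.93, 8.64 and 14.56 on average in control, LPA and LPA+IFNt.

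The interferon-stimulated antiviral list rose as a whole: 37 of the 41 measured members were higher and 0 lower, with a median log2 fold change of 3.15 (camera adjusted p = 4.44e-72, and 0.00118 with an estimated correlation). Adjusted over the list alone, 39 passed. The call held without each array in turn. In the list of interferon receptor, JAK-STAT and IRF genes 5 of 16 were higher, among them IRF9 (2.61, SE 0.19), STAT2 (2.45, SE 0.11), IRF7 (1.96) and IRF3 (0.87). The receptor genes IFNAR1 (0.01, adjusted p = 0.971) and IFNAR2 (0.17, adjusted p = 0.56) were not called. In the MHC class I list 10 of 16 were higher and 1 lower, with rises of the immunoproteasome genes PSMB9 (2.25, SE 0.19), PSMB8 (1.40) and PSMB10 (1.36) and of the peptide transporter gene TAP1 (1.93). Of the chemokines and cytokines 8 of 25 were higher, with TNFSF13B, CXCL10 (3.72, SE 0.60), CCL8 (3.13, SE 0.18) and IL15 (1.09) foremost. Of the apoptosis genes 2 of 15 were higher, the inflammatory caspase gene CASP4 (2.45) and CFLAR (1.23), which encodes an inhibitor of caspase-8. These 4 lists passed camera (adjusted p = 0.00025, 4.08e-12, 7.53e-07 and 0.002), and the calls were lost with an estimated correlation (adjusted p = 0.166, 0.083, 0.166 and 0.176). Adjusted over the list alone, 5 JAK-STAT and IRF genes were higher and 1 lower, 12 MHC class I genes higher and 1 lower, 10 chemokines and 4 apoptosis genes higher.

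Smaller changes stood in other lists. LGALS9, which encodes galectin-9, rose by 3.48 (SE 0.15) and IGFBP1 fell by 0.66 in the list of growth factors and implantation-related genes (1 of 34 higher, 1 lower, and 1 and 5 adjusted over the list alone, adjusted p = 0.617). The NF-kappaB targets TNFAIP6 (0.84) and NFKBIE (0.32) were higher, and the list stood at adjusted p = 0.0509, or 0.0333 with the replicate block and 0.712 with an estimated correlation, with 3 members higher adjusted over the list alone. It passed without control replicate 1 (0.0296), LPA replicates 1 (0.0466), 2 (0.0389) or 3 (0.0495), or LPA+IFNt replicate 2 (0.014). By probe set, NFKBIE had 1 of 4 called. CD40 was not called by its brightest probe set (-0.05), but 1 of its 2 was called higher (1.26). Among the immediate early genes 3 were higher and 2 lower of 18 (ZFP36 0.76, ATF3 0.38, IER2 0.34 and JUND -0.34, list adjusted p = 0.273), and 4 and 2 adjusted over the list alone. LPAR6 was lower by a log2 fold change of -0.52 (adjusted p = 0.0403), the only call among 12 genes of LPA receptors and metabolism (list adjusted p = 0.617), and LPAR1 (0.10), LPAR2 (-0.14), LPAR4 (0.04), LPAR5 (0.05) and ENPP2 (-0.30) were not called. No gene of the prostaglandin list passed (adjusted p = 0.617), with PTGS2 at -0.18 (adjusted p = 0.484), PTGR1 at -0.34 and PTGER4 at 0.65 (adjusted p = 0.0771, or 0.03 with the replicate block). OXTR, the oxytocin receptor gene, stood at -0.47 (adjusted p = 0.0984, or 0.023 with the block) in a list at adjusted p = 0.663, where PGR stood at 0.05. PGR lay under the highest trp value (2.80) on every array, so its value says nothing about a change.

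PLAUR was higher (0.39) and TNC lower (-0.33) in the protease and matrix list (adjusted p = 0.915), TPM2 lower (-0.52) among SRF and YAP targets (0.531), HMGCS1 lower (-0.18) among sterol synthesis genes (0.0991, or 0.0486 without LPA+IFNt replicate 3), MANF higher (0.30) and SEL1L lower (-0.26) in the ER stress list (0.585), and RRM1 lower (-0.27) among cell cycle genes (0.366). Of the stromal markers 3 of 15 fell, COL3A1 (-0.51, SE 0.05), COL1A1 (-0.39) and FBN1 (-0.39), which encode matrix proteins, and the list was lower with a median of -0.14 (adjusted p = 0.0109, 0.701 with an estimated correlation and 0.0515 without control replicate 2), with 4 lower adjusted over the list alone. Of the probe sets of COL1A1 and TNC, 1 of 2 was called lower and the other stood at 0.02 and 0.03, while COL3A1 had 2 of 2 called. The epithelial marker CDH1 rose by 0.21 and the epithelial list did not pass (16 genes, median 0.03, adjusted p = 0.366). CD53 (1.26) was the only leukocyte marker called (list adjusted p = 0.183). Lists of endothelial (0.663, PECAM1 -0.06, CLDN5 -0.18), red blood cell (0.273, ALAS2 0.06, HBA 0.04) and smooth muscle and pericyte markers (0.617, MCAM -0.22, DES -0.40) held no call, the first 2 with every marker under the trp value in control. For the other lists of these paragraphs the counts adjusted over the list alone equalled those over all genes. The protease list had a negative mean and median while its test pointed up, the steroid receptor list a mean of -0.02 and a median of 0.02, and the ER stress list a mean of 0.04 and a median of -0.01.

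**Figure D3:**
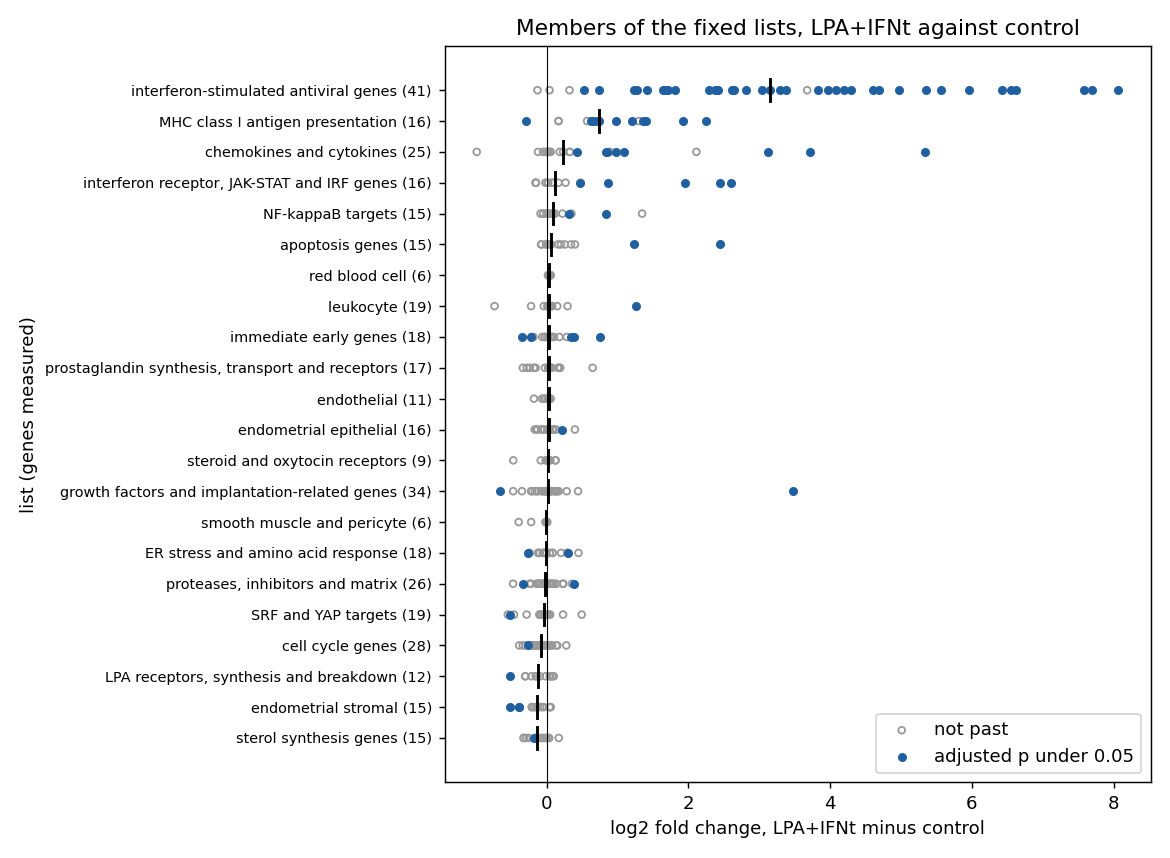
Log2 fold change in LPA+IFNt against control (x axis) of every measured member of the fixed lists (y axis, with the number of genes measured), with filled points for members past the threshold, open points for the others and black bars for list medians. The interferon-stimulated antiviral list has a median of 3.15, followed by MHC class I antigen presentation at 0.74.

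Falls were smaller than rises. PRUNE2 fell by 2.24 (SE 0.18, adjusted p = 0.000286), followed by MTURN (-1.91), EED (-1.57), the cyclin-dependent kinase inhibitor gene CDKN1C (-1.43), the integrin gene ITGAE (-1.22), IQSEC1 (-1.13), CIBAR1 (-1.13), MEDAG (-1.09), CHST9 (-1.05), FITM2 (-1.05), RRAD (-1.04) and BMP7 (-1.01). The annotation gives EED 23 probe sets, of which 4 were called lower and 2 higher, with log2 fold changes from -1.57 to 1.02, so EED has no single direction on this array. Only some probe sets were called for MTURN (2 of 5, the least changed at -0.09), CDKN1C (1 of 3, up to 0.03), IQSEC1 (1 of 4, up to 0.05), CHST9 (1 of 2, the other at -0.01) and BMP7 (1 of 2, the other at -0.57). In total 1282 probe sets passed, 595 higher and 687 lower, and 268 of the higher but 46 of the lower ones changed at least 2-fold. The median was 0.89 for higher calls and -0.47 for lower calls. The arrays of both groups lay apart for 23.1% of probe sets, where chance gives 10% for exchangeable arrays and the 3 other splits with the numbers kept apart gave 2.8% to 5.3%. The remaining splits, which part only 1 pair of equal number, gave 2.5% to 31.4%, so the highest lay above the real grouping.

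The count was 2085 with the replicate block, 791 without control replicate 2, and 534 with spike-in centring, which raised the median of all probe sets to 0.18 and left 457 higher and 77 lower. Of the 1282 probe sets, 425 were called with that centring and 3 changed sign without a call, while the standard error rose from a median of 0.0637 to 0.241 for every probe set. Which direction had more calls was not stable. There were 457 higher and 334 lower without control replicate 2, 490 and 391 without control replicate 1, 475 and 466 without LPA+IFNt replicate 1, 563 and 464 without replicate 2, and 481 and 427 without replicate 3, whereas the block gave 779 and 1306. Of 59 named genes called, 41 kept the call with each array left out in turn. IQSEC1, MEDAG, RRAD, IL15, NFKBIE, LPAR6, ATF3, IER2, TPM2, TNC, IGFBP1, HMGCS1, MANF, SEL1L, RRM1, CDH1, COL1A1 and CD53 did not, with highest adjusted p of 0.0511 to 0.134, most of them (17) without control replicate 2. With spike-in centring 17 named genes lost the call, COL3A1 (-0.35), COL1A1 (-0.23) and FBN1 (-0.23) among them, and the median of the stromal markers was 0.02. Of the 17, NFKBIE (0.48), ATF3 (0.54), IER2 (0.50), PLAUR (0.55), MANF (0.46) and CDH1 (0.37) had larger changes than in the main fit, and the others smaller ones. When the probe sets of each gene were averaged, EED (-0.13, adjusted p = 0.307), IQSEC1 (-0.34), NFKBIE (0.08), JUND (-0.11), TPM2 (-0.49), HMGCS1 (-0.15) and CDH1 (0.22) lost it.

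The last comparison, LPA+IFNt against LPA, asked what interferon tau added in the presence of LPA. The genes with the largest rise were the 12 that led against control, with PLAC8B at 8.36, IFI44 at 7.92, IFI44L at 7.85, MX2 at 7.54 (SE 0.06, adjusted p = 4.16e-10), USP18 at 7.11, LOC100298356 at 6.31, IFI6 at 6.29, ISG15 at 5.92, IFI27 at 5.67, RSAD2 at 5.38, TNFSF13B at 5.12 and MX1 at 5.12. LPA levels of PLAC8B, IFI44, MX2, LOC100298356 and CCL8 lay under the highest trp value (2.80), and counted from it their rises were 7.51, 7.40, 6.91, 5.95 and 2.54. Of the interferon-stimulated antiviral list 37 of 41 were higher and 0 lower (median 3.09, adjusted p = 5.4e-68, and 0.0014 with an estimated correlation), and 39 passed adjusted over the list alone. Higher members of other lists were STAT2 (2.47), IRF9 (2.46), IRF7 (2.07) and IRF3 (0.71), PSMB9 (2.25), TAP1 (1.83), PSMB8 (1.61) and PSMB10 (1.36), CCL8 (3.12), CXCL10 (3.11) and the interleukin gene IL18 (1.09), and CASP4 (2.24), CFLAR (0.82) and the death receptor gene FAS (0.54). In the JAK-STAT and IRF list 5 of 16, in the MHC class I list 10 of 16, of the chemokines 8 of 25 and of the apoptosis genes 3 of 15 were higher. These lists passed camera (adjusted p = 0.00532, 1.03e-10, 0.00383 and 0.00532) but not with an estimated correlation (adjusted p = 0.263, 0.11, 0.365 and 0.255). Without LPA replicate 2 the JAK-STAT and IRF list (0.0713) and the chemokines (0.0713) missed the threshold. Adjusted over the list alone, 6 JAK-STAT and IRF genes were higher and 2 lower, and 12 MHC class I genes, 8 chemokines and 4 apoptosis genes were higher.

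Genes that were lower with LPA+IFNt than with LPA included contractile, matrix and stromal genes. ACTA2, the gene of smooth muscle actin, was lower by a log2 fold change of -1.05 (SE 0.16, adjusted p = 0.00853) and TPM2 of -0.51, and the SRF and YAP targets were lower as a list (2 of 19 members, median -0.12, adjusted p = 0.00383, and 0.255 with an estimated correlation). VCAN (-0.49, adjusted p = 0.0391, or 0.0737 with the replicate block), TNC (-0.44), SERPINE2 (-0.26) and MMP1 (-0.21) were lower in the protease and matrix list (4 of 26, median -0.18, adjusted p = 0.0157, and 0.544 with an estimated correlation), and this list missed the threshold without LPA replicate 1 (0.0836), LPA replicate 3 (0.11) or LPA+IFNt replicate 2 (0.0603). Of the stromal markers 5 of 15 were lower, among them THY1 (-0.69, SE 0.08), COL1A1 (-0.55), COL3A1 (-0.54) and FBN1 (-0.40), with a list median of -0.25 (adjusted p = 6.22e-06, and 0.255 with an estimated correlation). The epithelial marker SPINT2 was lower as well (-0.45), and the epithelial list had a median of 0.05 (adjusted p = 0.651). Adjusted over the list alone, 4 SRF and YAP targets, 4 members of the protease list and 8 stromal markers were lower. With spike-in centring the median of all probe sets was 0.26, the medians of the SRF and YAP targets (0.12) and of the protease and matrix list (0.06) changed sign, and that of the stromal markers was -0.01. Of the genes named in this paragraph only ACTA2 kept its call then, while TPM2 (-0.26), VCAN (-0.25), TNC (-0.20), SERPINE2 (-0.02), MMP1 (0.03), THY1 (-0.44), COL1A1 (-0.30), COL3A1 (-0.29), FBN1 (-0.16) and SPINT2 (-0.21) lost it (adjusted p 0.473 to 0.957).

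The 12 largest falls among named genes were MTURN (-2.25, SE 0.30), UTP6 (-1.83, SE 0.20), PRUNE2 (-1.72), ANKH (-1.68, SE 0.12), the non-coding RNA gene MEG3 (-1.59), CDKN1C (-1.45), EED (-1.41), RRAD (-1.37), MEDAG (-1.37), SERPINF1 (-1.35), TCAF1 (-1.31) and the metalloproteinase inhibitor gene TIMP2 (-1.24). LGALS9 (2.94) and IGFBP3 (1.01), a binding protein of insulin-like growth factors, were higher and IGFBP1 (-0.85) and LGALS3 (-0.17) lower in the list of growth factors (2 of 34 higher, 3 lower, and 2 and 6 adjusted over the list alone, adjusted p = 0.584). IER2 (-0.71) and JUND (-0.33) were lower and ZFP36 (0.66) and JUN (0.42) higher among the immediate early genes (2 of 18 higher, 3 lower, and 4 and 3 adjusted over the list alone, adjusted p = 0.95). Of the 23 EED probe sets 4 were lower and 2 higher here as well. Only some probe sets were called lower for MTURN (2 of 5), MEG3 (2 of 5), CDKN1C (1 of 3), TIMP2 (2 of 3), ANKH (1 of 2) and TCAF1 (1 of 2). The same held for COL1A1 (1 of 2), TNC (1 of 2), TPM2 (1 of 2) and VCAN (1 of 3), while COL3A1 had 2 of 2 called. With probe sets averaged, EED (-0.20, adjusted p = 0.103), JUN (0.22), JUND (-0.10), TPM2 (-0.37) and VCAN (-0.56, adjusted p = 0.0506) lost the call. TNFAIP6 (0.65) was the only NF-kappaB target called (list 0.842), CD53 (1.15) the only leukocyte marker (0.842), and MANF (0.35) and SEL1L (-0.38) the only genes of the ER stress list (0.842).

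No gene of the LPA list passed (adjusted p = 0.939), with LPAR6 at 0.20, LPAR1 at 0.02, LPAR2 at -0.03, LPAR4 at 0.02, LPAR5 at -0.02, ENPP2 at -0.26 and PLPP3 at -0.24. None passed in the prostaglandin list either (0.651), with PTGS2 at -0.40 (adjusted p = 0.0949, or 0.0198 with the replicate block) and PTGDS at -0.51 (0.127, or 0.0414 with the block). The lists of steroid and oxytocin receptors (0.186), sterol synthesis genes (0.186) and cell cycle genes (0.0545, or 0.0217 with the block and 0.779 with an estimated correlation) held no call (PGR 0.04 but under the highest trp value on every array, SQLE -0.14, DHCR7 0.16). The cell cycle list passed without control replicate 2 (0.0466), LPA replicate 1 (0.0219), LPA replicate 2 (0.0021) or LPA+IFNt replicate 3 (0.0351). Single values changed by the block there were NCOA1 (0.30, adjusted p = 0.0599, or 0.0386 with it), RRM1 (-0.21, 0.0755, or 0.0195) and MCM3 (0.22, 0.0996, or 0.0248). Markers of endothelial (0.842, TEK -0.12, ERG 0.05), red blood cell (0.581, AHSP 0.05, HBB 0.03) and smooth muscle and pericyte cells (0.353, LMOD1 -0.06) held none, the first 2 with every marker under the trp value in control, with DES at -1.57 (adjusted p = 0.0526, 0.0204 with the block and 0.0469 with probe sets averaged). Over the lists alone, NCOA1 passed as higher and DES as lower. NCOA1 also passed with probe sets averaged (0.0174). DES has 1 probe set, so its own value was not averaged. The growth factor list had a mean of 0.02 and a median of -0.01, the leukocyte list -0.02 and 0.02, and the ER stress list -0.02 and 0.01. The receptor genes IFNAR1 (-0.33) and IFNAR2 (0.01) were not called.

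In this comparison 1571 probe sets passed, 614 higher and 957 lower, with 259 and 70 of them changed at least 2-fold. The arrays lay apart for 18.7% of probe sets, where chance gives 10% for exchangeable arrays and the 3 other splits with the numbers kept apart gave 1.3% to 3.5%. The remaining splits, which part only 1 pair of equal number, gave 3% to 28%, so the highest lay above the real grouping. The count was 954 without LPA replicate 1, 1004 with only the 6 arrays compared, and 680 with spike-in centring (581 higher and 99 lower). Of the 1571 probe sets, 494 were called with that centring and 66 changed sign without a call. The number of lower probe sets was 494 without LPA replicate 1, 1474 without LPA replicate 2, 626 without LPA replicate 3, 609, 592 and 605 without LPA+IFNt replicates 1, 2 and 3, and 1508 with the replicate block. Of 62 named genes called, 48 kept the call with each array left out. MEG3, SERPINF1, TCAF1, CXCL10, JUN, TPM2, VCAN, SERPINE2, MMP1, IGFBP3, LGALS3, CFLAR, FAS and CD53 did not (highest adjusted p 0.0513 to 0.125), 13 of them without LPA replicate 1. With spike-in centring 17 of the 62 lost the call: IER2, JUN, JUND, TPM2, VCAN, TNC, SERPINE2, MMP1, IGFBP1, LGALS3, SEL1L, MANF, SPINT2, THY1, COL1A1, COL3A1 and FBN1 (adjusted p 0.146 to 0.957). Of these, JUN (0.67) and MANF (0.59) had larger changes than in the main fit, and the others smaller ones, with IGFBP1 at -0.61.

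The responses to LPA and to LPA+IFNt were also set beside each other. Across probe sets their log2 fold changes against control correlated with r = 0.208, where simulated unchanged groups against the same 3 controls gave 0.5 on average. The 0.5 follows from sharing the controls, and changes in only 1 group lower r. An r under 0.5 therefore does not show that the responses were less alike than unchanged groups. The covariance was 0.0132 against 0.0061 in the simulation, which did not pair samples by replicate number. Of the 12 probe sets higher with LPA, 6 were also called higher with LPA+IFNt, where independent lists would share 0.297, and of the 5 lower ones 1, NUP214, was shared, where 0.143 would be. In 100 simulations without pairing, the 12 higher and 5 lower probe sets of lowest p with LPA stood for the calls. With both groups unchanged they shared 0.01 and 0 on average. With only LPA unchanged and the fitted changes of LPA+IFNt kept, they shared 4.02 and 2.82 on average and up to 8 and 5, though more probe sets were called with LPA+IFNt than in the data (3270 on average). With those changes kept, 0.05 probe sets on average (at most 1) were called in both comparisons, against 7 in the data. LPA calls themselves averaged 0.05 there, so whether the overlap comes from the shared control arrays stays open. When 50 probe sets were chosen without 1 replicate number, the LPA+IFNt array of that number moved in the chosen direction for 41, 31 and 36 of them (medians 0.30, 0.09 and 0.22). That choice did not use the control array of that number, but 3 numbers are too few to decide. IER2, AHSA1, SH3GLB1 and GTPBP4 were the named genes among the 6 probe sets called higher in both comparisons, IER2 with 1.05 in LPA and 0.34 in LPA+IFNt. ARPC1A (-0.05) and UFC1 (-0.02) had log2 fold changes near 0 in LPA+IFNt against control. Against LPA, 474 of the probe sets higher and 506 of those lower in LPA+IFNt against control were called in the same direction, and 5 probe sets were called in opposite directions, in comparisons that share the LPA+IFNt arrays. Of 2913 genes with several probe sets, 0, 4 and 5 had probe sets called in opposite directions in LPA against control, LPA+IFNt against control and LPA+IFNt against LPA.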

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

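The test of a smaller stromal share, the splits that keep equal replicate numbers apart and the centring on spike-in probe sets, alone or with the replicate block, were chosen only after the result was seen.

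Among the 112 control probe sets that the comparisons did not use, 1 differed between groups over 336 tests. The probe set for the 3' part of the elongation factor gene EF1A was lower in LPA+IFNt than in control by a log2 fold change of -0.267 (limma, adjusted p = 0.0421). The probe sets for the 5' part (0.045) and the middle part (0.016) of the same transcript did not pass.

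Other groupings of the arrays were fitted in the same way. For LPA against control the real grouping gave 17 probe sets and the highest of the other 9 splits gave 1, so 1 of 10 splits reached the real count. For LPA+IFNt against control 1 of 10 splits reached the real count of 1282 and the highest other gave 0, and for LPA+IFNt against LPA 1 of 10 reached 1571 and the highest other gave 1. These 10 splits are too few for a share under 0.05. The real grouping parts all 3 pairs of equal number, and the other splits that part 3 pairs gave 0 in each comparison, while those that part 1 pair gave at most 1. For the F test, 1 of 100 splits of the 9 arrays, the real one, reached 1439, where the draw disregarded the replicate numbers. The highest other count was 1024, and each of the 4 drawn splits that kept the LPA+IFNt arrays together gave at least 927, while the rest gave at most 4. Among the 36 splits that give each group 1 array of each replicate number, 1 reached 1439, again the real one, and the highest other was 1024. With the replicate number as a block the real split gave 2276 and the highest other 1331. A random grouping is therefore unlikely, though not excluded, as the source of this count, which rests mostly on the LPA+IFNt arrays. The 36 splits use a pairing that was inferred from the same data.

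Most of the probe sets called in LPA against control changed less in LPA+IFNt: 14 of the 17 kept under 50% of their change, with a median of 33.1%. Choosing the largest chance values would give such a loss in any other group. The 50 probe sets of smallest p were therefore also chosen without 1 replicate number. The LPA array of that number still moved further from its control than the LPA+IFNt array did. The median excess was 0.20, 0.18 and 0.41 for the numbers left out in turn. The replicate numbers are too few to decide, and pools of different numbers may share cows, so selection stays open. Signal of single probe sets stays open as well. Only 2 other probe sets of the called genes, those of ANKH and SLC25A5, had a mean level above 5. Their median change in the called direction was 0.02. A candidate biological explanation is that interferon tau opposes part of the response to LPA, which cannot be separated here from other differences between the groups without arrays of interferon tau alone.

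In LPA+IFNt against control 687 probe sets were lower, stromal markers among them, although the number fell to 334 without control replicate 2 and was then below that of higher ones (457). The normalization stays open as a source: the median of the probe sets not called was 0.018, but a quantile normalization fixes that value near 0, so the bound set for it beforehand decides nothing, with spike-in centring 77 lower calls were left (99 with the replicate block as well) while the standard error rose from a median of 0.0637 to 0.241 for every probe set, and the spike-ins were lower in LPA+IFNt in each pair of equal number (-0.14, -0.13 and -0.20). The stromal share of the cells would have to fall from 75% to 67.9% to lower the stromal markers by their median of -0.14, and would raise epithelial markers by 0.36. The epithelial markers had a median of 0.03 (95% bootstrap interval -0.07 to 0.10), below that rise. The interval resamples the markers and not the arrays, so it does not measure the spread between pools. The 75% is the seeded ratio of cells and was not measured in the RNA. A smaller stromal share therefore stays open. All 15 stromal markers (COL3A1 highest at 14.72) and 16 epithelial markers (EPCAM highest at 14.05) lay above the trp level in control, 1 stromal marker is also in another list, and lower expression in response to interferon tau remains untested.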

How the results depend on the processing

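Centring on spike-ins, alone or with the replicate block, and the block with an estimated correlation were added after the data were seen. Total counts not given here stayed within 1.5 times the reported ones. For LPA against control (17), the count was 89 with spike-in centring (113 with the replicate block as well), 53 above the median level, 31 above the lower quartile, 50 with trend and robust variances, 0 with no moderation (1476 at an unadjusted p under 0.05 of that ordinary t test), 449 with array weights, 11 with the replicate block, 28 with probe sets averaged, 1 with only the 6 arrays, 0 at adjusted p under 0.01 and 0 to 169 with an array left out. For LPA+IFNt against control (1282), it was 534 with spike-in centring (605 with the block as well), 788 with no moderation, 4757 with array weights, 2085 with the replicate block, 624 at 0.01, 616 at 1.5-fold and 791 to 1352 with an array left out. For LPA+IFNt against LPA (1571), it was 680 with spike-in centring (784 with the block as well), 901 with no moderation, 1004 with only the 6 arrays, 701 at 0.01, 725 at 1.5-fold and 954 to 2204 with an array left out. For the F test (1439), it was 734 with spike-in centring (821 with the block as well), 783 with no moderation, 4495 with array weights, 2276 with the block, 615 at 0.01 and 911 to 1997 with an array left out. Array weights gave control replicate 2 a weight of 7.28 and the other arrays 0.42 to 2.08. With an array left out, lower calls (687 and 957 against control and LPA) ranged from 334 to 730 and from 494 to 1474. Stricter thresholds lower a count by construction, and the cause of the other moves was not tested.

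Of 66 list tests 22 passed, 2 with an estimated correlation, 2 with the block and an estimated correlation, 12 with fry and 18 to 24 with an array left out. The block alone changed 2 list calls and 18 calls of named genes, each given beside its result, and no other call of a list or named gene. With no variance moderation 13, 16 and 11 named genes lost the call in the 3 comparisons, in the order given above, and 0 gained it. With only the 6 arrays compared 12, 8 and 13 lost it and 0, 3 and 1 gained it. The similarity of both responses (0.208) ranged from 0.154 to 0.304 with an array left out. With spike-in centring MMP1 (0.03116) and LGALS3 (0.07659) changed sign in LPA+IFNt against LPA and were not called, with or without the block. With the block as well, 5, 17 and 17 named genes lost the call in the 3 comparisons and 2, 1 and 1 gained it. The centring adds 1 shift to all probe sets of an array, so that limma gave all of them the same standard error (0.241, or 0.227 with the block, against a median of 0.0637 in LPA+IFNt against control), and calls lost or gained with it reflect this spread as well as the shift. That centring moved the median of all probe sets to -0.08, 0.18 and 0.26 in the 3 comparisons, and the higher share of calls to 46.1%, 85.6% and 85.4%, against 37.6% and 34.7% in the comparisons with LPA+IFNt when arrays were centred on their medians. The spike-ins themselves differed by 0.086, -0.159 and -0.245 between groups. For replicate numbers 1, 2 and 3 the differences were 0.03, 0.56 and -0.33 for LPA against control, -0.14, -0.13 and -0.20 for LPA+IFNt against control, lower in each pair (SD 0.039), and -0.17, -0.69 and 0.13 for LPA+IFNt against LPA. An exact permutation by sign flips of the 3 pairs gave p = 0.75, 0.25 and 0.5 (two-sided, smallest possible 0.25), too few to decide. Values that were not called and changed sign (55 of 4658 for named genes, 66 of 1182 for lists) are counted as kept. Of the tested probe sets 37.3% had a mean under the highest trp value, where changes are hard to see.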

Other observations

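The families below were formed after the data were seen, and the tests of carried-over RNA and of a single LPA array were chosen only after the result was seen.

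Genes were grouped into 88 families that share the letters of their symbol and hold at least 10 measured genes, and tested with camera as the lists were. In LPA+IFNt against control the tripartite motif genes were higher (adjusted p = 0.00656, and 0.397 with an estimated correlation), with 7 of 25 members higher and 1 lower. TRIM21 (2.61), an intracellular antibody receptor, TRIM34 (2.19), TRIM5 (1.71), TRIM38 (1.67), TRIM6 (1.33), TRIM56 (1.15) and TRIM25 (0.52) rose, and TRIM37 (-0.47) fell. TRIM5, TRIM21 and TRIM25 also belong to the interferon-stimulated list. The family median was 0.04 (0.20 with spike-in centring). In LPA against control no member passed.

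Genes of the large mitochondrial ribosomal subunit were slightly lower in LPA against control (43 MRPL genes, median -0.10, adjusted p = 0.000171). They were also lower in LPA+IFNt against control (median -0.12, adjusted p = 0.0159), where MRPL18 (-0.31) was the only member past the threshold. With spike-in centring the family median in LPA+IFNt against control changed sign to 0.03. Those of the small subunit were lower in LPA (24 MRPS genes, median -0.14, adjusted p = 0.00236), as were 20 nucleoporin genes of the NUP family (median -0.08, adjusted p = 0.00749), of which NUP214 passed. None of these held with an estimated correlation (adjusted p = 0.894 in LPA and 0.915 in LPA+IFNt). In LPA+IFNt the genes of the NDUFA family were lower (14 genes, median -0.13, adjusted p = 0.0378, and 0.915 with an estimated correlation), with a median of 0.03 under spike-in centring. NDUFA2 (-0.29) was the only member past the threshold.

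Interferon-stimulated genes stood slightly above control in LPA alone, with RSAD2 at 1.18 and ISG15 at 0.71 and a list mean of 0.08, or -0.01 with spike-in centring, and the list call was lost with an estimated correlation (adjusted p = 0.465). The list mean was 0.12, -0.01 and 0.13 in the LPA arrays of replicates 1, 2 and 3, and it was at least 0.06 with any 1 LPA array left out. Against the control array of the same number it was 0.07, 0.01 and 0.16, with a mean of 0.04 without number 3 (2 standard errors 0.11), and the list call was lost without LPA replicate 1 (adjusted p = 0.0687), LPA replicate 3 (0.197) or control replicate 3 (0.19), so dependence on single arrays stays open. RNA carried over from LPA+IFNt samples is another possible explanation: a common share of 0.41% left 17.9% of the 28 called members with a control level above 6 (5 genes) over 2 standard errors away. RSAD2 lay above that share's prediction of 0.47 and IFI6 (0.13) below its 0.43, which a common share would not give. A weak interferon response to LPA itself may also contribute and was not tested.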
